A study of Drosophila melanogaster with 2 samples.

How the data were processed

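Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, collected 4 to 24 h after egg laying, from a transgenic line that expresses tiptop (tio) fused to enhanced GFP. Tio is a zinc finger transcription factor and the paralog of teashirt (tsh). Per the labels, chromatin was sonicated to fragments of 200 to 800 bp, an anti-GFP antibody was used, and 2 biological replicates form 1 group. With 1 group there was no comparison between conditions, and the control library was not analysed here.

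The authors deposited peak lists on the genome builds dm6 and dm3. Per the notes deposited with each sample, a replicate list was made from the alignments of that replicate and 1 control, a pooled list from the alignments of both replicates and the control, and a thresholded list from the replicate and pooled lists by irreproducible discovery rate (IDR), a measure of rank agreement between replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak carries a signal value that is the authors' own, with a scaling that no source states. It served to describe, rank and filter peaks within a list, to compare matched peaks between the replicate lists and to set the medians of both builds side by side. Whether both replicate lists are on the same scale is unknown. Pooled values are not on the scale of the replicate values. Over the matched IDR peaks they were at a median of 2.01 times the mean of both replicates. The deposited q-value column holds -log10 q, and the deposited summit offset gives the summit in bp from the peak start. The number of reads per library is unknown, so no interval that needs depth is given.

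Replicate and pooled lists held 30000 regions each, background regions included. The IDR lists held 3793 peaks on dm6 and 3406 on dm3. On both builds every IDR peak was among the equally many highest-signal peaks of the pooled list, so repeating each analysis with those pooled peaks gave identical values by construction. Of the dm6 IDR peaks, 78.9% had the width of 436 bp, and 7 repeated the interval of another peak with a different summit and signal. The replicate lists shared 0 identical signal values. Coordinates are 1-based on dm6. Those on dm3 were never converted, and a dm3 genome was not used here.

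Summits were annotated with the Ensembl gene annotation of genome build BDGP6.54 and the matching genome sequence, on the 6 arms 2L, 2R, 3L, 3R, 4 and X, without transposable elements. Classes were assigned in the order promoter (within 1 kb of an annotated transcription start site, TSS), 5 prime UTR, 3 prime UTR, coding exon, other exon, intron and intergenic. A gene held a peak if a summit lay in its span extended 1 kb upstream. Positions were tested by circular permutation, that is shifts of all summits along each arm (1000 shifts, for which 0.0020 is the smallest p that a test of both directions can give). The 24 gene lists were tested against 100000 random lists of protein-coding genes matched on span in 20 bins, which amounts to permuting peak status within the bins, in both directions, with 2.00e-05 as the smallest possible p. The 24 consensus motifs were tested by exact McNemar tests of presence within 100 bp of the summit against a window centred 500 bp to 1 side. All 6-mers were ranked in peaks of even rank and the top 10 tested in peaks of odd rank. Arms were tested by exact binomial tests. Benjamini-Hochberg adjustment was applied within each family at 0.05. Peaks cluster and are not independent replicates, so binomial and McNemar p-values are too small and describe these libraries only. The list test treated genes as independent within span bins, although neighbouring genes can share a peak. Its p-values may therefore be too small as well.

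Lists, motifs, tests, the named-gene rule and the first set of alternatives were fixed before the data were examined, except for what follows. The upstream share of summits near TSSs, the promoter share by signal, the G+C content and the regions within 5 kb and 100 kb of tio and tsh were chosen after seeing the data. The rule named the 10 peaks with the highest signal, tio and tsh, the 3 members with the highest peak signal of each list past the threshold and the 1 such member of every other list, and the 5 genes with the most peaks. Of the list members, 6 symbols were updated to those of the annotation and 0 stayed unmatched. Alternatives covered the peak threshold, each replicate alone, matching distance, TSS window, gene assignment, background and build. In the alternatives a change of side was counted as a reversal only where 1 of both values passed the threshold.

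On simulated data, the shift test called 7 of 100 random summit sets and 20 of 20 sets with 10% of summits moved to TSSs. The list test called 0 of 1200 lists after adjustment when peaks depended on span alone. Without adjustment it called 50 of 50 lists of 40 genes with raised odds. Many of the lists tested here have fewer members, for which no such run was made. These simulations placed summits at random and drew peak status independently for each gene. They therefore say nothing of errors that come from clustered peaks or from peaks shared by neighbouring genes. The motif test called 0 of 24 motifs between shuffled windows, and the k-mer search ranked a planted 7-mer first. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.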

Results

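Binding of GFP-tagged Tio was profiled in whole embryos by ChIP-seq in 2 biological replicates of 1 group. The IDR list on dm6 held 3793 peaks, with a median signal of 145 and a range of 87.5 to 2078. The largest q-value in it was 0.0279. The dm3 list held 3406 peaks with a median signal of 155.

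The strongest peak lay on 3L (19590424 to 19590835), with its summit outside protein-coding genes and 117 bp from the TSS of CG14100, with a signal of 2078 in the pooled list, 1063 in replicate 1 and 1021 in replicate 2. The second, on 2L (480890 to 481295), lay in an intron of u-shaped (ush), which encodes a cofactor of GATA factors, and 1372 bp from the TSS of cabut (cbt). Its signal was 2018 in the pooled list, 1037 in replicate 1 and 974 in replicate 2. The sequence of 61 bp centred on the CG14100 summit read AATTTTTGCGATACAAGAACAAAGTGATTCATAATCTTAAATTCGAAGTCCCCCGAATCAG, and those on the ush summit read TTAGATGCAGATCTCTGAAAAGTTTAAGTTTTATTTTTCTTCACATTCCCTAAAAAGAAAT. The next 8 peaks lay nearest to the TSSs of HmgZ (2R, summit 21703451, also within HmgD), Ugalt (X, 2703882), Chro (3L, 22878895), px (2R, 22514300), CG11050 (2L, 6612719), Art3 (3R, 15229522), CG31145 (3R, 23669853) and Tcs5 (3L, 5139496). HmgZ and HmgD encode HMG-box proteins, Ugalt a UDP-galactose transporter and Chro a chromatin protein of interbands. Of the 10 peaks, those at ush and CG11050 were intronic and the others were classed as promoter. Their pooled signals ran from 1299 at Tcs5 to 2078 at CG14100, and each ranked among the first 13 of both replicate lists.

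The question of how far the replicates shared their peaks was addressed with equal numbers of top-ranked regions. Of the 3793 highest-signal regions of replicate 1, 2633 (69.4%) had a summit of the replicate 2 set within 100 bp, against 0.575% ± 0.124 (SD) for shifted summits (1-sided circular permutation test, p = 0.001, the smallest it can give). Among 3504 IDR peaks matched in both lists, Spearman's rho across peaks was 0.79, with no p-value because peaks are not replicates. The 95% bootstrap interval of 0.772 to 0.807 resampled single peaks. It may be too narrow because peaks cluster, and it does not measure the spread between libraries. The median log2 ratio of replicate 1 to replicate 2 was 0.16, with an SD of 0.46 across peaks. The signals of 173 peaks differed by more than 2-fold. The IDR list was itself chosen for concordance.

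**Figure D1:**
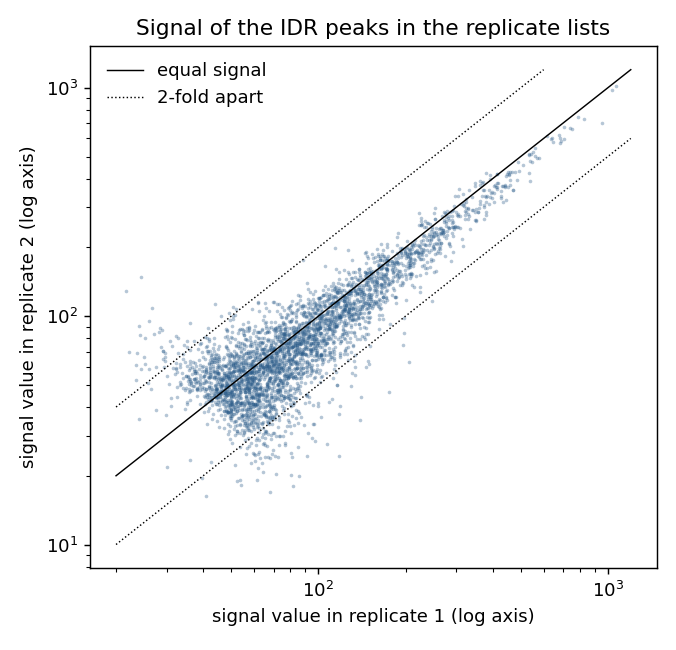
Signal of each matched IDR peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the authors' signal units, 1 point per peak. The solid line marks equal signal and the dotted lines 2-fold differences; 95.1% of the 3504 peaks lie between the dotted lines, and the spread is wider at low signal.

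Promoters held 1849 of the 3793 summits (48.7%), against 23.6% ± 1.03 (SD) of shifted summits (ratio 2.07, circular permutation test, adjusted p = 0.0035). In the same permutation test, coding exons held 7 summits (0.185%, against 9.92% shifted, adjusted p = 0.0035) and 3 prime UTRs 19 (0.501% against 4.21%, adjusted p = 0.0035). Intergenic sequence held 14% against 25.3% (permutation adjusted p = 0.0035), and 5 prime UTRs 0.158% against 0.445% (adjusted p = 0.0084). Introns held 35.8% against 36.1% (permutation adjusted p = 0.853), a comparison that passed the threshold, with a lower share than shifted summits, in the stronger peaks (ratio 0.866, adjusted p = 0.0028) and with replicate 2 alone (ratio 0.916, adjusted p = 0.0084). Other exons held 0.580% against 0.474% (permutation adjusted p = 0.513). The equally many lowest-signal regions of the pooled list gave another background, against which these classes were not tested. Of those regions, 2.82% lay in coding exons, 3.74% in 3 prime UTRs, 26.3% in intergenic sequence and 45.6% in introns. The promoter share was 66.7% among the 949 peaks with the highest signal and 36.4% among the 948 with the lowest, a trend that was not tested. Of 1661 summits within 1 kb of a protein-coding TSS, 1312 lay upstream of it (79.0% against 42.6% shifted, permutation p = 0.0020), with a median position of -182 bp.

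**Figure D2:**
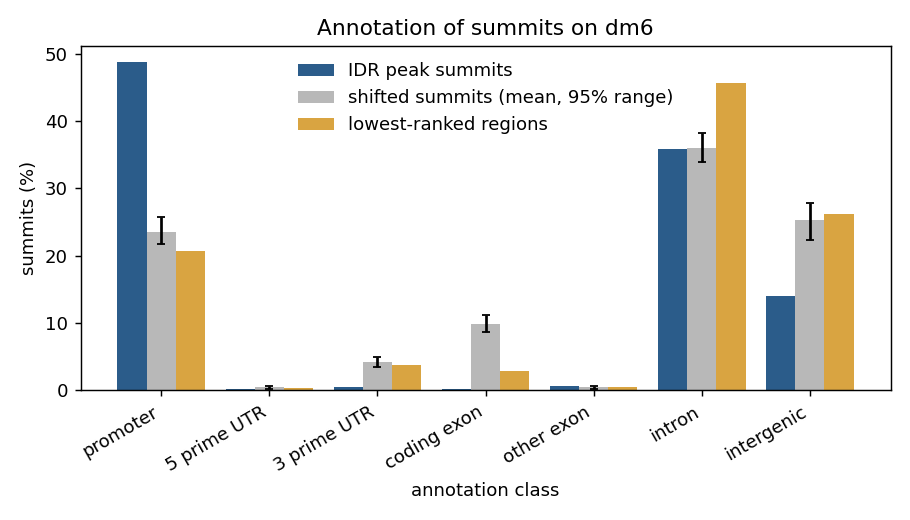
Percentage of summits (y axis) in each annotation class (x axis) for the IDR peaks, for shifted summits (mean, with bars for the 95% range of 1000 shifts) and for the equally many lowest-signal regions of the pooled list. The promoter bar stands at 48.7% for IDR peaks and 20.6% for the lowest-ranked regions.

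Peaks were denser than arm length predicts on 2L (756 peaks, ratio 1.13, exact binomial test, adjusted p = 3.16e-04) and 3L (865, ratio 1.09, adjusted p = 0.0101). They were sparser on 2R (611, ratio 0.853, exact binomial adjusted p = 5.37e-05), 3R (848, ratio 0.933, adjusted p = 0.0244) and the small arm 4 (15, ratio 0.393, adjusted p = 8.95e-05). The X held 698 (ratio 1.05, exact binomial adjusted p = 0.186) and passed the threshold only with replicate 1 alone (ratio 1.07, adjusted p = 0.0427). In the stronger peaks, where fewer were tested, 3L and 3R did not pass (ratios 1.07 and 0.933, exact binomial adjusted p = 0.162 and 0.160). With replicate 2 alone 3R did not pass either (ratio 0.963, exact binomial adjusted p = 0.243). Arm length was the full sequence of each arm, with no correction for parts to which few reads can be mapped.

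The tagged gene and its paralog were examined as a check of the label, since a transgene adds copies of the tagged gene. The check cannot decide, because the control library was not analysed here and may carry the same copies. Neither tio (2L, 22019208 to 22025734) nor tsh (2L, 21828593 to 21837011) held an IDR peak in its extended span. The nearest IDR summits lay 9992 bp from tio (22009216, signal 89.5) and 9589 bp from tsh (21846600, signal 168). Within 100 kb, 4 and 7 IDR peaks were found, the strongest at 22037001 (signal 222) and 21794958 (signal 521). Within 5 kb of tio, both replicates listed a region about 2 kb past the gene's end, of rank 3268 in replicate 1 (22027398, signal 54.4) and 7396 in replicate 2 (22027516, signal 30.8). The pooled list held 1 region within 5 kb of tio, at another position (22029676, signal 33.1, rank 24490). Within 5 kb of tsh it held 5 regions, with a highest signal of 44.3 (rank 12771), and each replicate 4, with a highest signal of 30.5 in replicate 1 (rank 9073) and 22.3 in replicate 2 (rank 15322).

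Peaks fell in the extended spans of 2256 of 13945 protein-coding genes (16.2%), of which 1504 held 1 peak and 112 held 5 or more. The most peaks were held by kirre (17), an adhesion gene of myoblast fusion, CG1677 (16), whose span also contains brk, ush (14), sbb (13) and shn (12). Per 10 kb this was 0.431 in kirre, whose span is 394149 bp, 1.28 in CG1677, 1.64 in sbb and 2.06 in shn. In ush the peaks lay from 479924 to 523144 on 2L, at 2.18 per 10 kb, with the second strongest of them at 480099 (signal 554). That summit also lay within 1 kb upstream of cbt, a gene inside ush whose 5 prime end is at 479688.

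**Figure D3:**
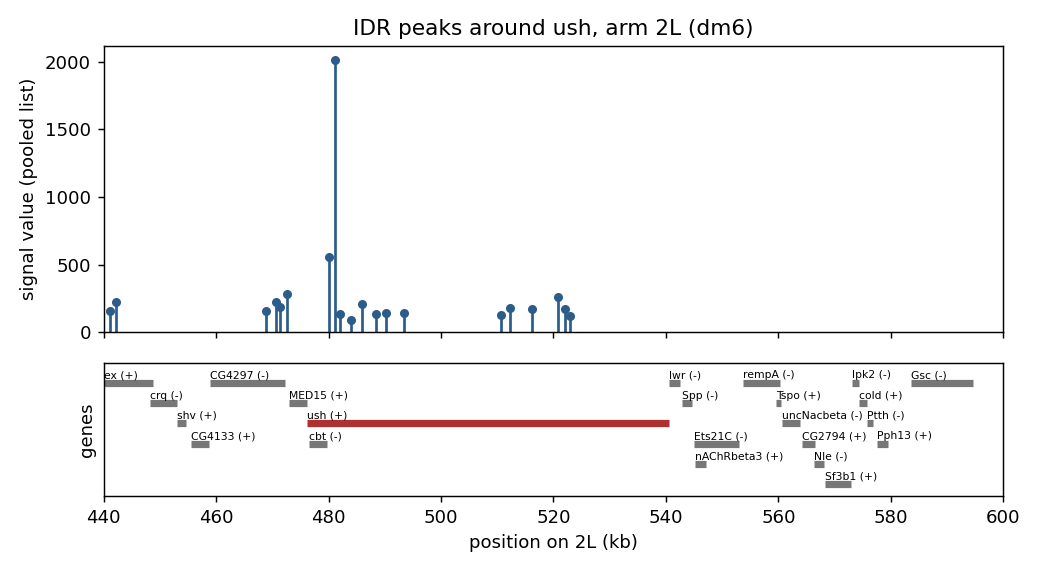
Map of 2L around ush (x axis, position in kb on dm6), with each IDR peak as a line at its summit and its height as the pooled signal value (y axis), above the protein-coding genes with their strand. The peak at 481060 reaches 2018, and the other peaks shown lie between 89.4 and 554.

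Genes of the EGFR pathway held peaks in 11 of 12 cases, against 4.78 ± 1.60 (SD) of span-matched genes (permutation test within span bins, adjusted p = 0.0019). They were spi, which encodes the EGF ligand Spitz (3 peaks, highest signal 617, and 350 and 263 in replicates 1 and 2), edl (4, signal 461), the secreted inhibitor aos (4, signal 426), and Egfr, vn, rho, S, Krn, pnt, aop and sty, while kek1 held none. Genes of the BMP pathway held peaks in 11 of 17 cases, against 5.64 ± 1.73 (permutation adjusted p = 0.0359). They included the repressor gene brk (2 peaks, highest signal 446), shn (12 peaks, signal 361) and the signal transducer Mad (1 peak, signal 348), and dpp, tkv, put, wit, Dad, sog, dally and cv-2. When only summits within 1 kb of a TSS of the gene were counted, neither list passed (EGFR ratio 2.37, permutation adjusted p = 0.117, and BMP ratio 1.14, adjusted p = 1), while the Notch list did (ratio 3.24, adjusted p = 0.0104). In the main assignment Notch pathway genes held peaks in 8 of 15 cases against 3.88 (permutation adjusted p = 0.0718), with the highest signal at E(spl)m3-HLH (684).

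Cytosolic ribosomal protein genes held peaks in 24 of 85 cases, against 6.64 ± 2.45 (SD) of span-matched genes (ratio 3.61, permutation adjusted p = 2.40e-04). The ratio was 1.75 without matching on span (Fisher exact adjusted p = 0.0156, permutation adjusted p = 0.0280). The highest signals were at RpS27 (544), RpL7 (323) and RpS20 (313). Proteasome genes, of similar span-matched expectation, held peaks in 2 of 48 cases (permutation adjusted p = 0.995), 1 of them Rpn5 (377). Chemosensory receptor genes held peaks in 3 of 179 cases, Or88a (208), Gr32a (157) and Ir41a (91.9), against 17.4 ± 3.83 (permutation adjusted p = 2.40e-04).

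The other 18 lists did not pass. Appendage patterning genes held peaks in 4 of 24 cases against 9.45, with hth highest (193), and differentiated neuron genes in 2 of 15 against 6.43, with ChAT highest (188). Both had a permutation adjusted p of 0.0767, and both passed with replicate 2 alone (adjusted p = 0.03 and 0.0251), the neuron list also when peaks went to the nearest TSS (0.0432). The appendage list was at a ratio of 1.04 with the nearest TSS (permutation adjusted p = 1) and of 1.03 without matching on span, where the neuron list was at 0.824 (Fisher exact adjusted p = 1 for both). Hox genes held peaks in 5 of 8 cases against 4.21, with Abd-B highest (244), and Hippo genes in 7 of 13 against 4.10, with yki highest (428). In the remaining lists the highest signals were at so (231) of retinal determination, ptc (121) of segmentation, gro (588) of Wnt, rdx (420) of Hedgehog, elav (560) of neural fate, stumps (355) of mesoderm, sls (349) of muscle structure, trh (273) of trachea, bowl (538) of Malpighian tubule and hindgut, grh (331) of epidermis, Hnf4 (358) of midgut, ush (2018) of hemocytes, piwi (271) of germline and Trl (1282) of Polycomb and trithorax.

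**Figure D4:**
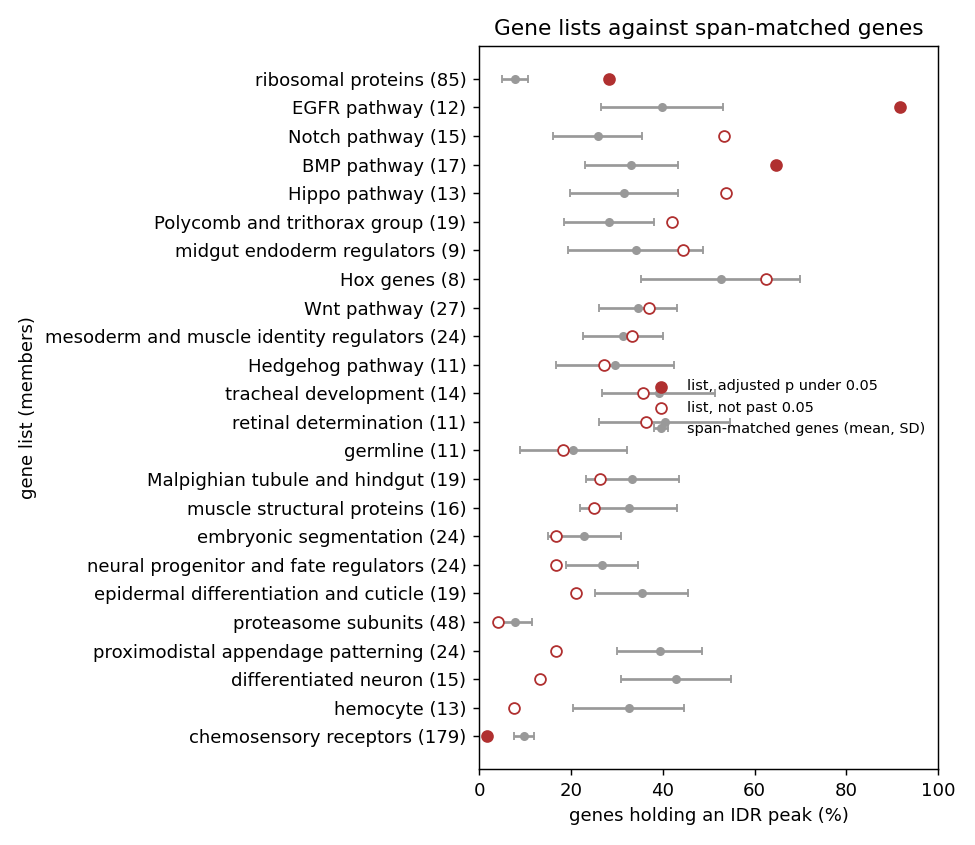
Percentage of the members of each gene list that held an IDR peak (x axis, red circles, filled where the adjusted p is under 0.05) beside the mean and SD of span-matched random lists (grey), with the number of members in parentheses (y axis). The EGFR list stands at 91.7% against 39.8% and chemosensory receptors at 1.68% against 9.72%.

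Summits were AT-rich. Windows of 201 bp had a mean G+C content of 33.8% ± 5.99 (SD across peaks), against 42.9% ± 8.38 in their flanks, and were lower than their flank at 79.9% of peaks. The lowest-ranked regions had 38.9%. In 25-bp windows G+C was 31% at the summit, 44.4% at 300 bp to the left and 44.0% at 300 bp to the right.

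**Figure D5:**
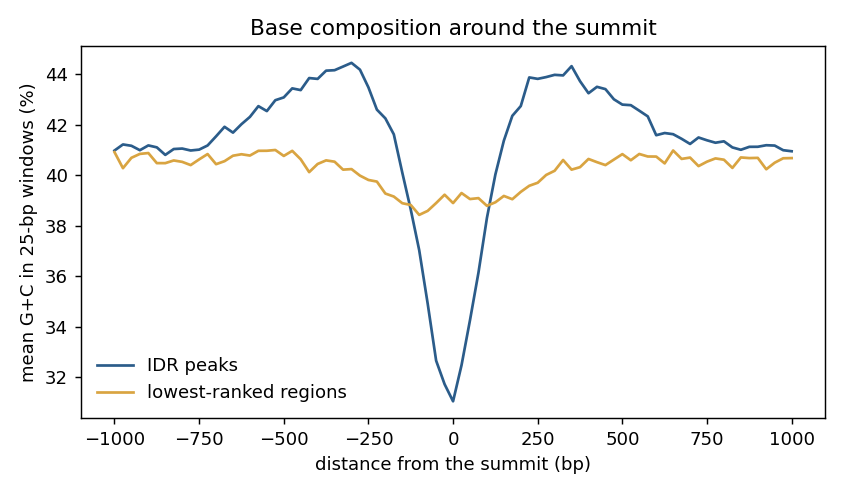
Mean G+C content in 25-bp windows (y axis) by distance from the summit in bp (x axis) for IDR peaks and for the lowest-signal regions of the pooled list. The IDR curve falls to 31% at the summit, and the other curve is at 38.9% there.

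Against flanks, 6 of 24 motifs were enriched. The homeodomain core TAATTA was present at 19.1% of summits against 11.9% (exact McNemar test, adjusted p = 4.08e-17), the Forkhead site at 15.6% against 9.62% (3.12e-14), the Exd-Hox site at 16.2% against 12% (1.27e-06), the DREF/BEAF-32 site TATCGATA at 1.48% against 0.527% (1.16e-04), CATATG at 8.91% against 7.20% (0.0185) and the GATA site at 3.48% against 2.5% (0.0378). The CA repeat (2.08% against 7.65%, exact McNemar adjusted p = 6.05e-29), the Trl site GAGAGAG (3.16% against 6.27%, 9.99e-10), CAGCTG (6.88% against 9.75%, 1.92e-05), the Ci site (1 against 12 windows, 0.0103) and the Hth/Meis site (5.83% against 7.12%, 0.0490) were depleted. Against summit windows shuffled with their dinucleotide counts kept, a background chosen after seeing the data, the Forkhead (ratio 1.37), DREF/BEAF-32 (4.00) and CATATG (1.54) sites stayed enriched, GATA did not pass (exact McNemar adjusted p = 0.395) and TAATTA was at a ratio of 0.95. Exd-Hox (ratio 0.850, exact McNemar adjusted p = 0.0026) and Sox (0.714, 0.0011) were depleted there, and the Trl, CAGCTG and CA repeat sites turned to ratios of 3.87, 2.51 and 4.39. M1BP, at a ratio of 1.82 against flanks (exact McNemar adjusted p = 0.102), passed against shuffled windows (5.17, 1.41e-04), with replicate 1 alone (2.83, 0.0044) and against the lowest-ranked regions (2.58, Fisher exact adjusted p = 0.0141), but not in the stronger peaks, with replicate 2 alone or within 50 bp (exact McNemar adjusted p from 0.145 to 0.687). Su(H), at a ratio of 0.724 against flanks (exact McNemar adjusted p = 0.0787), passed as depleted in the stronger peaks (0.0077), with replicate 2 alone (0.0189), with replicate 1 alone (0.0058) and within 50 bp (0.0265), but was at a ratio of 1.11 against shuffled windows (0.724). Scalloped/TEAD passed as depleted with replicate 2 alone (exact McNemar adjusted p = 0.0100) and within 50 bp (0.0265), the initiator within 50 bp (0.0296), and Pangolin/TCF against the lowest-ranked regions (Fisher exact adjusted p = 0.0159). CATATG and Hth/Meis did not pass with either replicate alone (adjusted p from 0.208 to 0.438), nor did Ci (0.0842 with each) or, with replicate 2 alone, GATA (0.0713). Among the stronger peaks only TAATTA, Forkhead and Exd-Hox passed as enriched (exact McNemar adjusted p = 0.0632 for DREF/BEAF-32, 0.450 for CATATG and 0.0620 for GATA), and within 50 bp of the summit DREF/BEAF-32 and GATA did not pass (0.590 for both). All 10 leading 6-mers against flanks passed in the held-out peaks and were made of A and T only, led by TTAAAA (54.0% against 26.1%, exact McNemar adjusted p = 3.97e-65). Against shuffled windows 10 of 10 passed as well, but only 2 were made of A and T, and CAGTGC was among the others (16.8% against 4.96%, exact McNemar adjusted p = 7.15e-33).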

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

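The dm3 IDR list was used for counts, for signal and, on the main arms, as an alternative in the rank correlation between replicates (0.793). It held 4 peaks outside the main arms, which that correlation left out. They lay on 2RHet (signal 180 and 110), XHet (133) and U (112), and no explanation was tested.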

How the results depend on the processing

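Alternatives that used dinucleotide-shuffled or GC-matched backgrounds, matching on nearby TSSs, the permutation test without matching on span, and those for classes, arms, 6-mers and the upstream share were chosen after seeing the data. The number of genes with a peak (1521 to 2486), the promoter share (36.3% to 57.3%) and the sharing between replicates kept their direction or stayed within 1.5 times under every alternative run. With summits at most 50 bp apart the rank correlation moved to 0.82, above the bootstrap interval over single peaks. In the stronger 0.5 of the peaks, 3 arms and 3 enriched motifs passed, with fewer peaks tested. Without matching on span, 8 lists were enriched in a Fisher exact test and in the permutation test, with 2 depleted in the former and 1 in the latter, and 2 were depleted when peaks went to the nearest TSS. Leaving out a replicate gave 1 to 3 depleted lists, 3 without replicate 1. Against shuffled windows 2 motifs were depleted, Exd-Hox and Sox, neither of them among the 5 depleted against flanks. There the ratio turned to 0.850 for Exd-Hox, 0.95 for the homeodomain core, 3.87 for Trl, 2.51 for CAGCTG and 4.39 for the CA repeat. Against the lowest-ranked regions it turned to 1.43 for Trl, 1.00 for CAGCTG and 0.711 for POU. Both backgrounds are poorer in G+C than the flanks, and beyond this the cause was not tested. Without the pooled peaks, which are the IDR peaks themselves, 175 results per gene list kept their side of the threshold, 15 newly passed and 2 no longer passed. Of those per motif, 105 kept it, 12 newly passed and 19 no longer passed. The unknown read depth limits what can be said of weak peaks.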

Other observations

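The lists and tests of this part were chosen after the main results were seen, except that the predictions for both ribosomal protein tests were written before those tests were run. Of 11 further gene lists, mitochondrial ribosomal protein genes held peaks in 15 of 73 cases against 4.78 ± 2.07 (SD) of span-matched genes (ratio 3.14, permutation adjusted p = 8.80e-04), with the highest signals at mRpS10 (1376), mRpL41 (1268) and mRpL23 (841). These summits also fell in the extended spans of Art3, CG8079 and CG9004, and 15 of the 15 genes shared a peak with another gene, against 48.0% of all genes with a peak. With matching on nearby TSSs the ratio was 2.32 (permutation p = 0.0025). The other 10 did not pass. In the insulin and TOR list and in the list of other highly expressed genes described below, 1 member each had no match in the annotation. Ecdysone response genes held peaks in 9 of 10 cases against 5.41 (permutation adjusted p = 0.0842), among them Hr3 (668), Hr4 (454) and Eip75B (395). Toll and Imd genes held peaks in 7 of 13 against 3.23 (0.0842), highest at imd (482). JNK genes held 6 of 12 against 3.28 (0.241), highest at Mkk4 (865), and cell cycle genes 6 of 15 against 3.17 (0.241), highest at CycE (344). Insulator and promoter architecture genes held 4 of 13 against 2.12 (0.440), highest at Chro (1524). Axon guidance genes held 10 of 15 against 8.07 (0.609) and insulin and TOR genes 4 of 12 against 3.31 (permutation adjusted p = 1). JAK-STAT genes held 3 of 10 against 2.66 (1) and apoptosis genes 2 of 13 against 2.32 (1).

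Summits also lay between head-to-head gene pairs, whose starts are at most 1 kb apart. Of 2326 such pairs 263 (11.3%) held a summit. Upstream intervals of the same lengths, drawn at random protein-coding genes outside such pairs, held a summit in 3.44% of cases (95% range 2.67% to 4.17%), and 2 of them together in 6.74% (5.80% to 7.78%). Among intervals clear of other protein-coding genes this was 4.26% (3.44% to 5.07%) and 8.28% (7.18% to 9.46%). Head-to-head promoters may thus hold summits more often than other promoters, beyond having 2 starts, although genes were not matched on expression. A first comparison with shifted summits was set aside, because shifting also moves summits off the upstream side of TSSs.

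Base composition was weighed as the source of the promoter and exon shares. Random positions matched on G+C lay within 1 kb of a TSS in 22.3% of cases, against 48.7% of summits, and in coding exons in 2.5%, against 0.185%. The G+C content of the 201-bp window alone thus accounts for neither share. It could account for much of the step from 9.93% of random positions in coding exons to 2.5%. Dinucleotides and the higher G+C beside the summit were not matched, so other aspects of composition stay open. No biological explanation was tested.

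A 7-mer search against dinucleotide-shuffled summits was led by CAGTGCA. It was found in 10.2% of held-out summits against 1.63% of shuffled ones (ratio 6.26, exact McNemar adjusted p = 2.28e-30). This argues against the base and dinucleotide composition of whole windows, but shuffling does not keep the AT-rich centre. Against unshuffled sequence the contrast was smaller. Of all summits, including those used to choose the 7-mer, 10.3% held it, against 3.32% of flanks (ratio 3.11) and 4.09% of the lowest-ranked regions. Among all 1944 summits more than 1 kb from a TSS, which include peaks used to choose the 7-mer, 13.6% held it. The share in their flanks was 2.93% (ratio 4.63, exact McNemar p = 5.67e-35), which argues against a promoter element. Of the occurrences of CAGTGCA within 140 bp of the summit, 7.97% lay within 20 bp, against 11.1% for 7-mers of the same base content without CAGTG (ratio 0.716, Fisher exact p = 0.0160, after a first comparison with an even spread that ignored the AT-rich centre). The 7-mer was thus not concentrated at the deposited summits. A site of the tagged protein there cannot be excluded, because summits may be less exact than 20 bp. Of the top-ranked replicate 1 summits, 54.7% had a replicate 2 summit within 50 bp and 77.1% within 250 bp. The median distance of the 7-mer from the summit was 57.5 bp, against 49.5 bp in shuffled windows (95% bootstrap interval of the difference -7 to 19 bp). This interval was added to the criterion after a first run without it had counted against a motif of the tagged protein. Shuffling spreads the AT-rich centre over the window, so this comparison cannot decide on a site beside the summit. A site of another protein bound at the same regions was not tested.

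The peaks at ribosomal protein genes were weighed against transcription level and promoter crowding. Of 35 other highly expressed genes, 31.4% held a peak against 15.5% of span-matched genes (permutation p = 0.0229, adjusted p = 0.0842 over the 11 lists), with the highest signals at Fer1HCH and Fer2LCH (1 shared peak, 720) and Gapdh2 (561). Without sta and Rack1, which belong to the ribosome, 11 of 33 held a peak (permutation p = 0.0172). Signal at highly transcribed genes whatever the tagged protein may thus account for the pattern. Proteasome genes, whose expression was not examined here, showed no excess (2 of 48 against 3.71 of span-matched genes, ratio 0.538). The ribosomal ratio of 3.61 was also above the 2.02 of the 35 genes, a difference that was not tested. For ribosomal protein genes, matching on nearby TSSs left a ratio of 2.40 (permutation p = 6.00e-05). Counting gene starts in place of TSSs, which was run first, gave 3.05 (permutation p = 2.00e-05), so crowding does not account for all of the pattern. Binding of Tio at these genes stays open, since no untagged or other-tag library was analysed here.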
